A study of Mus musculus with 36 samples.

How the data were processed

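Whole brains of wild-type C57BL/6 mice were profiled by RNA sequencing at day 19, the peak of disease, in 36 libraries. Per the labels' protocols, EAE was induced by subcutaneous immunization with a myelin oligodendrocyte glycoprotein peptide in complete Freund's adjuvant with pertussis toxin. Mice were then left untreated (n = 9), given corn oil by gavage (n = 9) or given farnesol in corn oil at 100 mg per kg per day by gavage (n = 10), and naive mice (n = 8) were the healthy controls. Total RNA was extracted with RNeasy columns and made into libraries with a NEBNext Ultra kit, per the labels' protocols. Replicate numbers name animals within a group and do not pair animals between groups.

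The authors deposited 1 table of raw counts of reads per gene, with 54532 Ensembl gene identifiers and 1 column per library. Per the submitters' processing notes, reads were mapped with STAR 2.5 to mm10. The extraction protocol also mentions Kallisto, and the read counter, the annotation release and the use of strand are not given in the sources used here. Symbols and coordinates (GRCm38) were taken from GENCODE M21 by gene identifier, which named 54409 identifiers holding 99.94% of counts. Total counts ranged from 14.71 M to 24.21 M per library, with means (M) of 19.8 in naive, 20.5 in untreated, 20.5 in vehicle and 18.8 in farnesol libraries. Mitochondrial transcripts made up 5.1 ± 0.45% of counts in naive, 4.4 ± 0.5% in untreated, 4.5 ± 0.26% in vehicle and 4.6 ± 0.35% in farnesol libraries.

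Genes were kept with filterByExpr of edgeR 4.0.16 (R 4.3.3; minimum count 10, minimum total 15), which left 18438. Libraries were scaled by TMM factors, and 1 quasi-likelihood model with a mean per group was fitted to all 36 libraries (glmQLFit and glmQLFTest). Each of 6 comparisons was adjusted by Benjamini-Hochberg over the genes tested, and adjusted p below 0.05 was called changed with no minimum fold. SE is the log2 change divided by the square root of the F statistic. CPM values are means and SDs over libraries.

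Gene lists for cell types, brain regions, immune, stress, lipid and housekeeping functions were written from general knowledge before the data were examined. Of 48 lists, 47 had at least 4 tested genes. They were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg over lists in each comparison. Each library was scored as the mean log2(CPM + 0.5) of a list, and scores were compared by two-sided exact permutation over all arrangements of the libraries, adjusted over the 47 lists. The smallest possible exact p was 4.11e-05 for 9 against 8 libraries. The counts adjusted over the list alone used Benjamini-Hochberg on the edgeR p-values of the list's genes only.

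The disease signature was drawn from a fit of the 17 untreated and naive libraries, as the 500 changed genes of smallest p in each direction, and was tested by camera in a fit of the farnesol and vehicle libraries only. Its score was the mean log2 CPM of rising genes minus that of falling genes.

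Genes named in the text follow a rule fixed before the data were examined. It takes, in each comparison, up to 10 of the largest rises and 10 of the largest falls by log2 change among genes with adjusted p below 0.05 and a mean of at least 1 CPM in either group, leaving out predicted or unnamed loci. It adds up to 4 genes of smallest p of each list described, and Mbp, Gfap, Aif1, Cd74, Fdps and Ppargc1a. A further gene of the rule is not reported here. Genes named outside the rule are said to be chosen after the values were seen. No fold is given for genes with 3 or fewer counts in all libraries of a group.

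Alternatives fixed before the data were examined were RLE scaling, DESeq2 1.42.0, limma-voom with sample weights, other count filters, a fit of only the groups compared, replicate number as a block, 1 surrogate variable (sva 3.50.0), leaving out each library in turn, an estimated correlation in camera, fry, a larger or otherwise drawn signature, a pooled control and a score pseudocount of 2. Alternatives added after seeing the data were library set as a term, libraries of 1 set only, leaving out libraries low in cerebellar genes (more than 1 log2 below the group median), and leaving out libraries with Sbp above 1 CPM. The library sets were defined by the gap in CT010467.1 between 2820 and 5160 CPM, and no source used here names a batch.

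The pipeline was tested on simulated data with the mean of each gene over all libraries, its fitted dispersion and the real library sizes. Of genes set to differ in farnesol libraries, 46% were recovered at 1.25-fold, 68% at 1.5-fold, 78% at 2-fold and 98% at 4-fold (50 genes each), with 4 false calls. Genes simulated without change numbered 18238, and 18235 of all simulated genes passed the count filter. Each gene was drawn independently, without library sets or shared differences between animals, so these rates may not hold for the real libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Clinical scores and other tissues were not analysed here.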

Results

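Whole-brain RNA was compared between naive mice (n = 8) and mice at the peak of experimental autoimmune encephalomyelitis (EAE) that were left untreated (n = 9), gavaged with corn oil vehicle (n = 9) or gavaged with farnesol (n = 10). Changes are log2 ± standard error (SE), expression is mean ± SD in library-size-scaled counts (CPM), p is two-sided, and adjusted p is from edgeR unless another test is named. EAE brains differed from naive brains in at least 4586 genes in each of the 3 comparisons. Vehicle gavage differed from no gavage in 4 genes, and farnesol differed from vehicle in 17 genes. No group was given the adjuvant and toxin alone, so their effects were not told apart from those of the disease.

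The libraries fell into 2 sets that the labels do not name, seen in the ribosomal RNA gene CT010467.1 (chr17:39846353-39848827, GRCm38). It measured at most 2820 CPM in all untreated and vehicle libraries and in farnesol replicates 1 to 3 (set 1), and at least 5160 CPM in farnesol replicates 4 to 10 and all naive libraries (set 2). Untreated and vehicle brains were therefore compared with naive brains only across the sets, and farnesol with vehicle or untreated brains mostly across them. Farnesol against naive could be measured inside set 2, and vehicle against untreated lay wholly inside set 1.

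**Figure D1:**
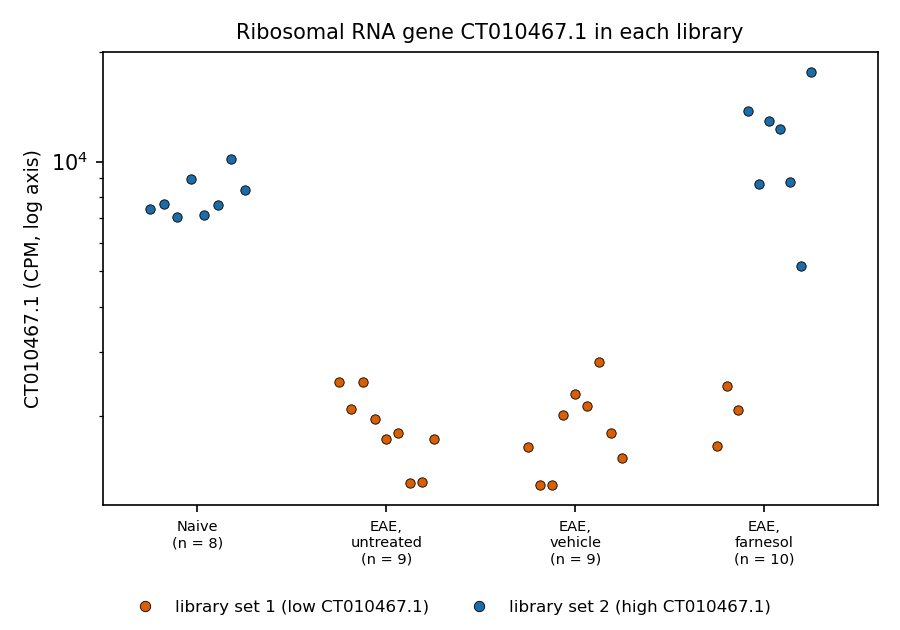
CPM of the ribosomal RNA gene CT010467.1 in each library (log axis), with a 1.83-fold gap between library set 1 and library set 2.

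In untreated EAE, an acute phase gene, an interferon-induced chemokine gene and the endothelial selectin genes were among the largest rises. Lcn2, which encodes the iron-binding acute phase protein lipocalin 2 (ENSMUSG00000026822, chr2:32384633-32388252), rose by 7.70 ± 0.41, from 0.222 ± 0.212 CPM in naive brain (n = 8) to 46.6 ± 16.9 CPM (n = 9; adjusted p = 1.96e-16). Cxcl9, an interferon-induced chemokine that attracts T cells, rose by 7.24 ± 1.43 (adjusted p = 0.000284). Selp, the P-selectin that lets leukocytes roll on inflamed endothelium, rose by 6.23 ± 0.84 (adjusted p = 2.01e-06). Sele, the matching E-selectin, was nearly absent from naive brain (0.0171 ± 0.0484 CPM) and reached 2.02 ± 1.90 CPM (adjusted p = 3.34e-05). The same held for Serpina3f, a serine protease inhibitor of the acute phase type (0.0068 ± 0.0192 against 2.49 ± 1.09 CPM), and Il18r1, a receptor chain for interleukin 18 (0.00861 ± 0.0244 against 1.02 ± 0.879 CPM). Ly6i and Clec4e, myeloid surface proteins, had 0 counts in all 8 naive libraries and 1.74 ± 1.54 and 1.10 ± 0.628 CPM in untreated EAE.

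In that comparison 4586 genes changed (2505 rose, 2081 fell), 620 of the rises and 50 of the falls by more than 2-fold. Cd74, the invariant chain of MHC class II, rose by 4.67 ± 0.77, from 7.90 ± 1.37 to 202 ± 146 CPM (adjusted p = 3.28e-05). Gfap, the intermediate filament of astrocytes, rose by 1.35 ± 0.29, from 249 ± 29.6 to 632 ± 231 CPM (adjusted p = 0.000646). Aif1, a marker of microglia and macrophages, rose by 1.24 ± 0.33 (adjusted p = 0.00536). Mbp, a main protein of compact myelin, measured 3060 ± 495 against 3260 ± 357 CPM and did not pass (-0.09 ± 0.09, adjusted p = 0.505). Ppargc1a, a coactivator of mitochondrial genes, fell by 0.16 ± 0.06 (adjusted p = 0.0369). Fdps, the synthase of farnesyl diphosphate, did not pass (0.01 ± 0.28, adjusted p = 0.989).

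Most gene lists of infiltrating leukocytes and of their recruitment rose in untreated EAE by camera with its preset correlation. All 12 measured neutrophil genes rose (12 adjusted over the list alone). They comprised the calgranulin genes S100a9 (3.90 ± 0.35) and S100a8 (3.97 ± 0.42) and the granule protein gene Ngp (3.42 ± 0.35). The neutrophil score, a mean log2 over the list, was 2.15 ± 0.57 against 0.02 ± 0.11 (exact p = 4.11e-05, the smallest possible; adjusted p = 0.000322), and all 9 untreated libraries lay above every naive one. Of 13 endothelial activation genes 11 rose, 0 fell and 2 did not pass (11 rose adjusted over the list alone). Lrg1, a secreted glycoprotein of activated vessels, rose by 3.37 ± 0.22 from 1.23 ± 0.368 to 12.9 ± 3.82 CPM (adjusted p = 1.48e-13), and the adhesion receptor gene Icam1 by 2.44 ± 0.30. Of 17 monocyte and macrophage genes 14 rose, 0 fell and 3 did not pass (15 rose adjusted over the list alone). They were led by Plac8 (5.08 ± 0.59) and the chemokine receptor gene Ccr2 (3.28 ± 0.41; list adjusted p = 0.0821 with an estimated correlation). Of 15 T cell genes 11 rose, 0 fell and 4 did not pass (12 rose adjusted over the list alone). They included Cd3g of the T cell receptor complex (3.92 ± 0.80) and Foxp3 of regulatory T cells (1.36 ± 0.28; list adjusted p = 0.188 with an estimated correlation). Of 14 chemokine genes 11 rose, 1 fell and 2 did not pass (11 rose and 1 fell adjusted over the list alone), with Cxcl1, which attracts neutrophils, up by 5.51 ± 0.66 (list adjusted p = 0.103 with an estimated correlation). Of 6 B cell and plasma cell genes 3 rose, 0 fell and 3 did not pass (4 rose adjusted over the list alone), and neither camera nor the score passed (0.55, exact p = 0.0331, adjusted p = 0.0576). Without the 5 untreated libraries that carried Sbp transcripts, described with farnesol against untreated brains, the B cell score differed by 1.17 and passed (exact p = 0.00202, adjusted p = 0.005). Those 5 had the lower B cell scores, at 0.66 to 1.19 against 1.9 to 2.11 in the untreated libraries kept, so this exclusion favoured a larger difference. Across all 47 lists, only the neutrophil and endothelial activation calls held with an estimated correlation in each of the 3 comparisons with naive brain.

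Antigen presentation, complement, interferon and reactive astrocyte genes rose with them. Of 11 MHC class II genes 10 rose, 0 fell and 1 did not pass (10 rose adjusted over the list alone), with the beta chain gene H2-Ab1 up by 4.28 ± 0.73 (list adjusted p = 0.188 with an estimated correlation). The MHC class II score was 2.09 higher (exact p = 4.11e-05). Of 16 complement genes 15 rose, 0 fell and 1 did not pass (16 rose adjusted over the list alone), with the central component C3 up by 4.67 ± 0.70 and the protease gene C1s1 up by 3.19 ± 0.30 (list adjusted p = 0.0821 with an estimated correlation). All 18 interferon gamma induced GTPase genes rose (18 adjusted over the list alone), among them Gbp2 (2.75 ± 0.62) and Gbp5 (2.33 ± 0.52), which act against intracellular pathogens (list adjusted p = 0.195 with an estimated correlation). Of 20 reactive astrocyte genes 15 rose, 0 fell and 5 did not pass (16 rose adjusted over the list alone). Examples were Steap4 (2.75 ± 0.31), a metalloreductase, and Osmr (1.21 ± 0.18), the oncostatin M receptor (list adjusted p = 0.0821 with an estimated correlation). All 9 untreated libraries scored above every naive one for each of these 4 lists.

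**Figure D2:**
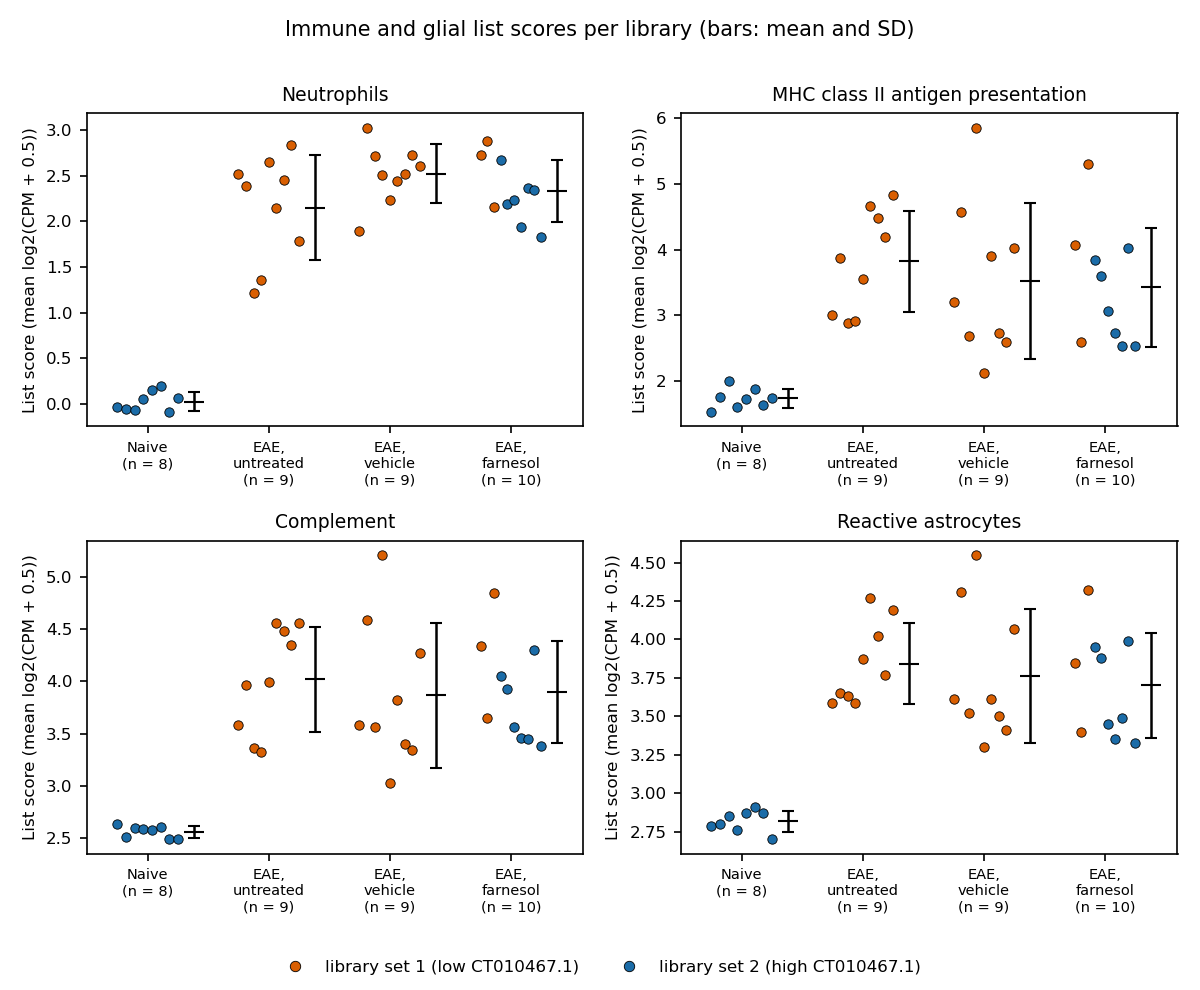
List scores of neutrophils, MHC class II, complement and reactive astrocytes in each library, with group mean and SD. Every EAE library lay above the naive range, which was -0.09 to 0.20 for neutrophils and 2.49 to 2.64 for complement.

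Transcripts of cholesterol synthesis fell in untreated EAE while most glucocorticoid response genes and some chaperone genes rose. Of 25 mevalonate pathway genes 0 rose, 19 fell and 6 did not pass (20 fell adjusted over the list alone). The fallen genes included Sqle, squalene epoxidase (-0.39 ± 0.06, adjusted p = 7.01e-06), and Dhcr7, which makes cholesterol from its last precursor (-0.39 ± 0.06, adjusted p = 3.45e-06). The mevalonate score was 5.13 ± 0.04 against 5.39 ± 0.05 (exact p = 4.11e-05), below every naive library in 9 of 9 (camera adjusted p = 0.0786 with an estimated correlation). Of 17 glucocorticoid response genes 13 rose, 0 fell and 4 did not pass (14 rose adjusted over the list alone). The transcription factor gene Cebpd rose by 1.59 ± 0.16, the kinase gene Sgk1 by 1.11 ± 0.21 and the lipid droplet gene Plin4 by 2.54 ± 0.48 (list adjusted p = 0.119 with an estimated correlation). The glucocorticoid score differed by 0.66 over all 9 untreated libraries and by 0.34 over the 4 without Sbp transcripts. Of 20 heat shock and unfolded protein genes 9 rose, 1 fell and 10 did not pass (10 rose and 1 fell adjusted over the list alone). Hspa5, the endoplasmic reticulum chaperone BiP, rose by 0.48 ± 0.08, from 272 ± 18.0 to 378 ± 29.7 CPM (list adjusted p = 0.195 with an estimated correlation). The heat shock score was 6.17 to 6.4 in untreated EAE and 5.95 to 6.1 in naive brains. Vehicle-treated (5.9 to 6.22) and farnesol-treated EAE (5.83 to 6.15) overlapped the naive range, so by score only untreated EAE lay wholly above naive brains. Of 13 mitochondrially encoded transcripts 0 rose, 9 fell and 4 did not pass (11 fell adjusted over the list alone), such as mt-Atp6 of the ATP synthase (-0.95 ± 0.13) and mt-Nd1 of complex I (-0.35 ± 0.07; list adjusted p = 0.12 with an estimated correlation).

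Some marker genes of neurons, glia and olfactory bulb also fell. Slc1a2, the main astrocytic glutamate transporter, fell by 0.47 ± 0.06, from 2930 ± 253 to 2110 ± 162 CPM (adjusted p = 1.84e-07). Of 15 homeostatic astrocyte genes 0 rose, 5 fell and 10 did not pass (1 rose and 9 fell adjusted over the list alone; list adjusted p = 0.188 with an estimated correlation). Of 15 inhibitory neuron genes 0 rose, 5 fell and 10 did not pass (6 fell adjusted over the list alone), with the GABA-synthesizing enzyme genes Gad1 (-0.24 ± 0.05) and Gad2 (-0.31 ± 0.07; list adjusted p = 0.123 with an estimated correlation). Of 22 myelin genes 0 rose, 2 fell and 20 did not pass (2 fell adjusted over the list alone), namely Cnp (-0.30 ± 0.08) and Opalin (-0.47 ± 0.14). The myelin score did not pass (-0.15, exact p = 0.146; camera adjusted p = 0.605 with an estimated correlation). Of 12 olfactory bulb genes 0 rose, 7 fell and 5 did not pass (8 fell adjusted over the list alone; list adjusted p = 0.195 with an estimated correlation). Omp, the olfactory marker protein gene, fell by 2.69 ± 0.49, from 5.10 ± 4.02 to 0.779 ± 0.743 CPM, and Cdhr1, a cadherin of mitral cells, fell by 1.37 ± 0.38. Single libraries also differed in regional genes such as those of cerebellum, and dissection was not told apart from disease for the olfactory bulb list.

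The disease call of untreated brains moved most with library set as a term in the fit. That term was estimated from the farnesol libraries alone, 3 of set 1 and 7 of set 2. Their disease signature scores ran from -2.36 to -1.34 in set 1 and from -2.80 to -1.95 in set 2. The term therefore cannot tell library set apart from differences in disease between those animals. With it, 175 genes were called and the SE was 1.70-fold larger. Of the 4586 changed genes 4299 (93.7%) kept their sign, while their median size went from 0.30 to 0.21. Lcn2 (7.49), Lrg1 (3.43), S100a9 (3.43), Selp (5.95), Slc1a2 (-0.47) and Cebpd (1.44) still passed, and Cd74 (3.01), Gfap (0.84), Sqle (-0.22) and Hspa5 (0.22) no longer did.

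Vehicle-gavaged EAE brains also differed from naive brains, where 5808 genes changed (3011 rose, 2797 fell; 655 rises and 25 falls by more than 2-fold). Lcn2 rose by 7.69 ± 0.41 (adjusted p = 2e-16), Cxcl9 by 7.83 ± 1.40, and Saa3, an acute phase apolipoprotein of macrophages, by 6.04 ± 1.08, from 0.0453 ± 0.0608 to 3.46 ± 6.28 CPM. Sele went from 0.0171 ± 0.0484 to 2.69 ± 2.41 CPM, and F10, coagulation factor X, had 0 counts in all 8 naive libraries and 1.81 ± 2.20 CPM in vehicle-treated brains. Cd74 rose by 4.63 ± 0.77 (adjusted p = 2.46e-05), Gfap by 1.12 ± 0.29 (adjusted p = 0.00275) and Aif1 by 1.12 ± 0.33 (adjusted p = 0.00895). Chil3, a lectin of alternatively activated macrophages, rose by 5.62 ± 0.79, and the interferon-induced chemokine gene Cxcl10 by 5.11 ± 0.89. Mbp (-0.09), Fdps (0.26) and Ppargc1a (-0.09) did not pass.

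All 12 neutrophil genes rose in vehicle-treated EAE (12 adjusted over the list alone), with S100a9 up by 4.40 ± 0.35. The list score was 2.52 ± 0.32 (exact p = 4.11e-05). All 11 MHC class II genes rose (11 adjusted over the list alone; list adjusted p = 0.358 with an estimated correlation), as did all 16 complement genes (16 adjusted over the list alone; list adjusted p = 0.154 with an estimated correlation). Of 22 excitatory neuron and synapse genes 0 rose, 13 fell and 9 did not pass (13 fell adjusted over the list alone). Examples were Syn1, a synaptic vesicle phosphoprotein (-0.36 ± 0.07), and Syp, synaptophysin (-0.32 ± 0.05). That score was 8.80 ± 0.07 against 9.01 ± 0.05, below every naive library in 9 of 9 (exact p = 4.11e-05; camera adjusted p = 0.154 with an estimated correlation). Of 12 cerebral cortex genes 0 rose, 6 fell and 6 did not pass (7 fell adjusted over the list alone), with the layer 4 nuclear receptor gene Rorb at -0.49 ± 0.08 (list adjusted p = 0.358 with an estimated correlation). Slc1a2 fell by 0.56 ± 0.06 (adjusted p = 6.33e-09), and 17 of 25 mevalonate genes fell, 0 rose and 8 did not pass (17 fell adjusted over the list alone; list adjusted p = 0.154 with an estimated correlation). Of 17 glucocorticoid response genes 12 rose, 0 fell and 5 did not pass (14 rose adjusted over the list alone), with the leucine zipper gene Tsc22d3 up by 0.62 ± 0.11 (list adjusted p = 0.154 with an estimated correlation). Of 20 proliferation genes 10 rose, 0 fell and 10 did not pass (11 rose adjusted over the list alone), with the cell cycle marker gene Mki67 up by 1.21 ± 0.26 (list adjusted p = 0.366 with an estimated correlation).

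With set as a term, again estimated from the farnesol libraries alone, 684 genes were called between vehicle-treated and naive brains. Of the changed genes 95.2% kept their sign. Lcn2 (7.48), S100a9 (3.94), Slc1a2 (-0.55), Syn1 (-0.42) and Rorb (-0.63) still passed, and Cd74 (2.96), Gfap (0.62), Saa3 (4.87) and Cxcl9 (6.04) no longer did.

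Farnesol-treated EAE brains showed the disease changes against naive brains, with 6297 changed genes (3299 rose, 2998 fell; 674 rises and 25 falls by more than 2-fold). Lcn2 rose by 7.62 ± 0.41 to 44.2 ± 12.5 CPM (n = 10, adjusted p = 2.34e-16), and by 7.56 among the 7 farnesol and 8 naive libraries of set 2. Lilr4b, an inhibitory receptor of myeloid cells, rose by 5.56 ± 0.61 (5.11 inside set 2), and Lrg1 by 3.44 ± 0.22 (3.46 inside set 2). Cd74 rose by 4.12 ± 0.75 (3.40 inside set 2), Gfap by 0.98 ± 0.28 (0.82 inside set 2) and Aif1 by 1.12 ± 0.33 (0.84 inside set 2). Each of these genes passed inside set 2 as well, where 4872 genes changed (2573 rose, 2299 fell). Mbp (-0.07), Ppargc1a (-0.09) and Fdps (0.53 ± 0.27) did not pass over all libraries, and Fdps passed inside set 2 at 0.79.

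All 12 neutrophil genes rose in farnesol-treated EAE (12 adjusted over the list alone), with S100a9 up by 4.17 ± 0.35. The score was 2.34 ± 0.34 against 0.02 ± 0.11 (exact p = 2.29e-05, the smallest possible; 10 of 10 libraries above every naive one). The score difference was 2.31 over all libraries and 2.20 inside set 2. Of 11 MHC class II genes 9 rose, 0 fell and 2 did not pass (11 rose adjusted over the list alone; score difference 1.70, and 1.46 inside set 2; list adjusted p = 0.365 with an estimated correlation). All 16 complement genes rose (16 adjusted over the list alone; score difference 1.33, and 1.17 inside set 2; list adjusted p = 0.209 with an estimated correlation). Of 25 mevalonate genes 0 rose, 17 fell and 8 did not pass (1 rose and 18 fell adjusted over the list alone), with Dhcr7 at -0.43 ± 0.05 and Sqle at -0.41 ± 0.06. The mevalonate score was 5.13 ± 0.12 over all 10 libraries and 5.19 ± 0.06 in the 7 of set 2, against 5.39 ± 0.05 in naive brains (exact p = 2.29e-05; list adjusted p = 0.115 with an estimated correlation).

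Activity-dependent and neuronal genes fell in farnesol-treated EAE relative to naive brains. Of 18 immediate early genes 0 rose, 11 fell and 7 did not pass (12 fell adjusted over the list alone; list adjusted p = 0.263 with an estimated correlation). The score was 4.81 ± 0.18 against 5.33 ± 0.18 (-0.52 overall and -0.53 inside set 2; exact p = 0.00016; 7 of 10 libraries below every naive one). Fos, a component of the AP-1 transcription factor, fell by 1.04 ± 0.23, from 40.8 ± 6.26 to 19.9 ± 6.81 CPM (adjusted p = 0.000829). Egr1, a zinc finger factor induced by neuronal firing, fell by 0.78 ± 0.14 (adjusted p = 4.05e-05). Of 15 inhibitory neuron genes 0 rose, 8 fell and 7 did not pass (10 fell adjusted over the list alone), with Gad1 at -0.27 ± 0.05 (list adjusted p = 0.163 with an estimated correlation). Syn1 fell by 0.40 ± 0.06, among 22 excitatory neuron genes of which 0 rose, 12 fell and 10 did not pass (12 fell adjusted over the list alone; list adjusted p = 0.239 with an estimated correlation). Aplnr, the apelin receptor of endothelium, fell by 1.66 ± 0.35, Pcdh12, an endothelial protocadherin, by 2.05 ± 0.34, and Omp by 3.18 ± 0.50. Of 12 olfactory bulb genes 0 rose, 9 fell and 3 did not pass (11 fell adjusted over the list alone; list adjusted p = 0.239 with an estimated correlation). Their score differed by -0.94 over all libraries and -1.08 inside set 2, and here too dissection was not told apart from disease.

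**Figure D3:**
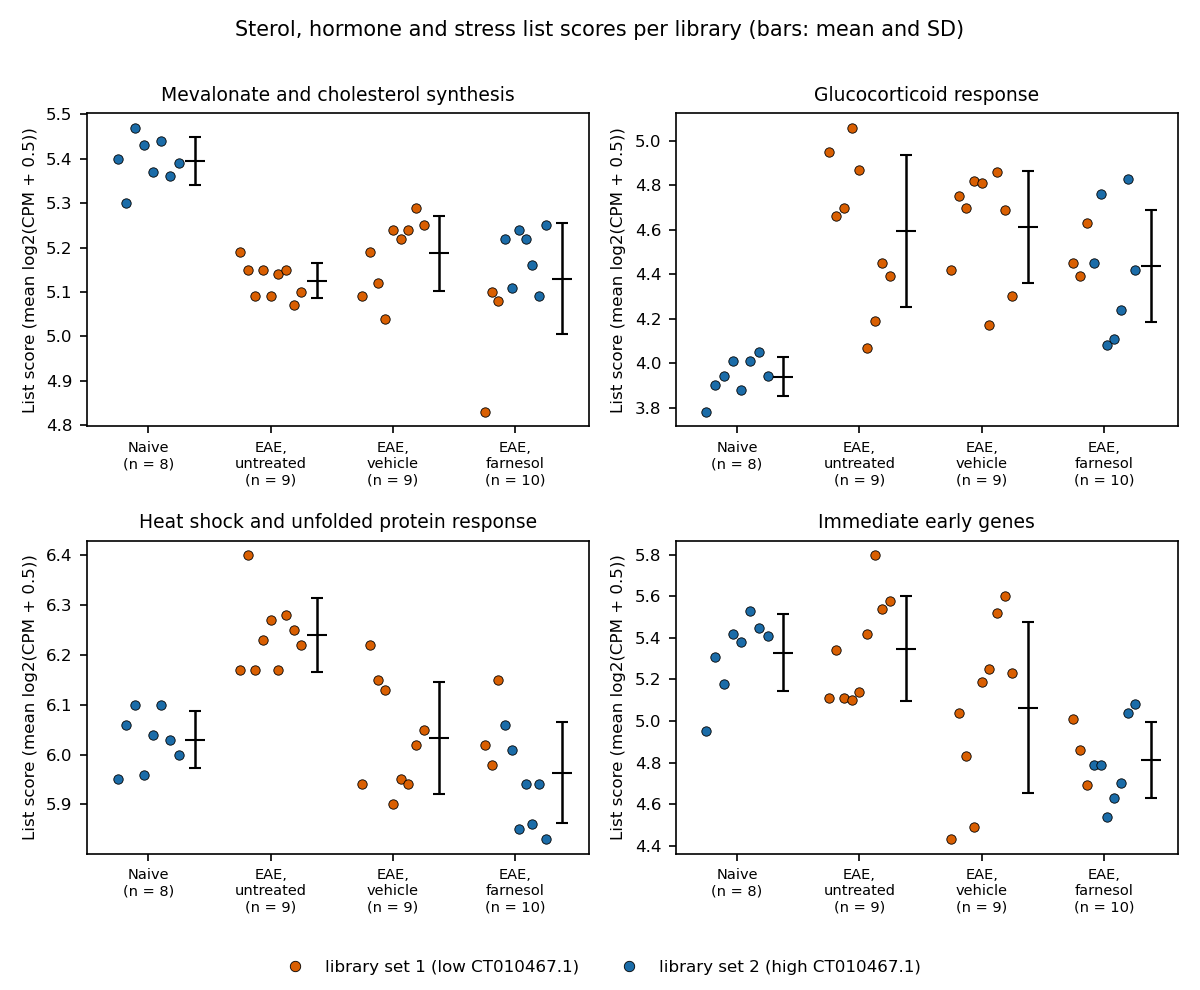
List scores of the mevalonate pathway, glucocorticoid response, heat shock and unfolded protein response and immediate early genes in each library. The heat shock score was 6.17 to 6.40 in untreated, 5.90 to 6.22 in vehicle-treated and 5.83 to 6.15 in farnesol-treated EAE, and 5.95 to 6.1 in naive brains.

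Vehicle gavage against no gavage, both inside set 1, changed 4 genes, all lower with gavage (adjusted p = 0.0391 each). Ier5, a stress-induced gene that acts on heat shock factor 1 (chr1:155096361-155099636), fell by 0.43 ± 0.08, from 86.9 ± 5.44 to 64.4 ± 7.65 CPM (n = 9 each). Fmnl1, a formin that shapes actin in leukocytes (chr11:103171107-103198901), fell by 0.34 ± 0.07. Synj2, an inositol phosphatase of vesicle recycling (chr17:5941280-6044290), fell by 0.30 ± 0.06, and Kcnip3, a calcium-binding regulator of potassium channels (chr2:127456498-127522094), by 0.28 ± 0.05. Genes rising numbered 0 by edgeR, 1522 genes in all had unadjusted p below 0.05, and DESeq2 called 43 and voom 15.

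The heat shock and unfolded protein score was lower with vehicle gavage, at 6.03 ± 0.11 against 6.24 ± 0.07 (exact p = 0.000452, adjusted p = 0.0213), and 8 of 9 vehicle libraries lay below the lowest untreated one. It was the only list of 47 whose score passed, and its camera call held with an estimated correlation (adjusted p = 0.00882). None of its 20 genes passed over all genes, and 13 fell adjusted over the list alone. Hspa5 measured 295 ± 43.2 against 378 ± 29.7 CPM (-0.36 ± 0.08, adjusted p = 0.067). Dnajb1, an HSP40 cochaperone, was -0.26 ± 0.05 (adjusted p = 0.0509). Manf, a neurotrophic factor released under endoplasmic reticulum stress, was -0.28 ± 0.06 (adjusted p = 0.0641), and Hyou1, a hypoxia-induced chaperone, -0.22 ± 0.05 (adjusted p = 0.0652). At its preset correlation camera passed 11 lists in all, 5 higher and 6 lower with gavage. They included immediate early genes, whose score did not pass (-0.28, exact p = 0.0997; camera adjusted p = 0.402 with an estimated correlation), and cerebral cortex genes (-0.16, exact p = 0.0133, adjusted p = 0.166; camera adjusted p = 0.338 with an estimated correlation). Cd74 (-0.04 ± 0.59), Gfap (-0.23), Aif1 (-0.12), Fdps (0.25), Ppargc1a (0.08) and Mbp (0.00) did not pass.

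The 4 calls between vehicle and untreated brains rested on single libraries. The count was 0 without any one of untreated replicates 1, 2, 5 and 8 or vehicle replicates 1, 4, 5, 6 and 9, 1 without untreated 3, 2 without untreated 4 or vehicle 7, 8 without untreated 7, 9 without untreated 6, 11 without vehicle 3 and 15 without vehicle 2.

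Farnesol against vehicle was the primary comparison, and 17 genes changed (15 rose, 2 fell; 10 rises by more than 2-fold). Nfil3, a basic leucine zipper repressor of circadian and immune genes (chr13:52967209-52981073), fell by 0.45 ± 0.09, from 13.2 ± 1.98 (n = 9) to 9.61 ± 1.11 CPM (n = 10; adjusted p = 0.0289). Plat, tissue plasminogen activator (chr8:22757727-22782844), fell by 0.24 ± 0.05, from 37.6 ± 2.51 to 31.9 ± 2.00 CPM (adjusted p = 0.0477). Slc6a6, the taurine transporter (chr6:91684053-91759066), rose by 0.23 ± 0.05, from 135 ± 9.51 to 159 ± 15.9 CPM (adjusted p = 0.0467). Inside set 1, with 3 farnesol libraries against 9 vehicle libraries, Nfil3 was -0.48, Plat -0.31 and Slc6a6 0.35, and none of them passed.

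Most of the rising genes were noncoding transcripts, and 12 of the 14 besides CT010467.1 lay higher in farnesol libraries of set 2 than in those of set 1. CT010467.1 rose by 2.21 ± 0.30 (adjusted p = 0.000107), and Rn7sk, the small nuclear RNA that restrains transcription elongation (chr9:78175303-78175633), by 2.05 ± 0.28 (adjusted p = 0.000107). Lars2, the mitochondrial leucyl-tRNA synthetase (chr9:123366927-123462666), rose by 1.58 ± 0.23, from 184 ± 44.3 to 552 ± 280 CPM (adjusted p = 0.000249). Malat1, a nuclear speckle RNA (chr19:5795690-5802672), rose by 0.84 ± 0.15. Lncpint, a p53-induced noncoding RNA (chr6:31082565-31220488), rose by 0.89 ± 0.18, and Kcnq1ot1, an imprinted antisense RNA (chr7:143203458-143296549), by 0.53 ± 0.10. Muc6, a gastric mucin (chr7:141633456-141655319), rose by 1.38 ± 0.30, and mt-Atp6 by 0.62 ± 0.12. The other 6 rising genes were predicted or cDNA-named loci, mentioned after the values were seen, namely Gm23935 (1.73), Gm24270 (1.73), Gm24187 (1.89), 9530059O14Rik (1.49), D830024N08Rik (1.10) and Gm37352 (1.43). Gm23935, Gm24270 and Gm24187 are nearly identical 57-base loci, so reads cannot be placed among them with certainty. Inside set 1 the difference from vehicle was 0.13 for Lars2, 0.48 for Rn7sk and 0.34 for Malat1. Mean Lars2 was 201 ± 51.7 CPM in farnesol libraries of set 1 (n = 3), 702 ± 171 in those of set 2 (n = 7) and 395 ± 37.4 in naive brains. Malat1 was 1130 ± 80.8, 1800 ± 408 and 950 ± 64.4 CPM in the same groups, so that naive brains of set 2 lay near the vehicle value of 894 ± 189. Kcnq1ot1 differed from vehicle by 0.45 in farnesol libraries of set 1, 0.55 in those of set 2 and -0.08 in naive brains.

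Genes of the farnesol pathway and of EAE pathology did not pass between farnesol and vehicle. Fdps was 0.27 (adjusted p = 0.998). Cd74 was -0.51 ± 0.58 (138 ± 161 against 196 ± 293 CPM), Gfap -0.14, Aif1 -0.01, Mbp 0.02 and Ppargc1a -0.01 (adjusted p = 0.998 for Cd74, Gfap, Mbp and Ppargc1a). The exact score test passed 0 of 47 lists and 0 had unadjusted p below 0.05 (smallest exact p = 0.0612). Camera passed 9, and 0 of those held with an estimated correlation or passed with fry. Camera placed immediate early genes lower, whose score was 4.81 ± 0.18 against 5.07 ± 0.41 (exact p = 0.0966; 0 of 18 genes passed, and 3 fell adjusted over the list alone; list adjusted p = 0.679 with an estimated correlation). It also placed glucocorticoid response genes lower (score difference -0.18, exact p = 0.145; 0 of 17 genes passed, and 5 fell adjusted over the list alone; list adjusted p = 0.679 with an estimated correlation). The mevalonate score was 5.13 ± 0.12 against 5.19 ± 0.08 (-0.05, exact p = 0.303; camera adjusted p = 0.987 with an estimated correlation). Inside set 1 it was 5.01 ± 0.15 against 5.19 ± 0.08 (-0.18, exact p = 0.0273, adjusted p = 0.374). Genes of prenylation and isoprenoid use, 0 of 15 of which passed over all libraries or adjusted over the list alone, differed in score by -0.02 (exact p = 0.224). Inside set 1 that difference was -0.08 (exact p = 0.00455, the smallest possible; adjusted p = 0.214). The 3 farnesol libraries of set 1 included replicate 1, lowest in mevalonate genes (4.83), and replicate 2, low in cerebellar genes. Neutrophils (-0.18, exact p = 0.242), MHC class II (-0.09, exact p = 0.846), myelin (0.00, exact p = 0.991) and T cells (0.00, exact p = 0.996) did not differ by score.

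Inside set 1 edgeR called 0 genes between farnesol and vehicle, with 2227 genes at unadjusted p below 0.05. With set as a term 1 gene was called, none of the 17, whose median size went from 1.38 to 0.33. Over all libraries the count of 17 was 8 without vehicle replicate 2 or farnesol replicate 6, 9 without farnesol 8, 10 without vehicle 5 or farnesol 4 or 10, 11 without vehicle 3, 4, 8 or 9, and 36 without farnesol 3.

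The genes of EAE as a whole were also followed between farnesol and vehicle. The 500 strongest rises and 500 strongest falls of the untreated and naive libraries were taken as a disease signature and tested in farnesol and vehicle libraries only. The rising genes had a median of -0.07 in farnesol, with 118 of 500 above 0 (camera p = 0.00451, and p = 0.639 with an estimated correlation). The falling genes had a median of 0.023, with 323 of 499 above 0 (camera p = 1.48e-05, and p = 0.259 with an estimated correlation). Inside set 1 the direction was the opposite, with a median of 0.219 for the rising genes, 436 of 500 above 0 (camera p = 1.05e-10), and -0.031 for the falling genes (camera p = 0.0293). The per-animal score was -2.21 ± 0.46 with farnesol and -2.13 ± 0.52 with vehicle (exact p = 0.727), and inside set 1 -1.82 ± 0.51 against -2.13 ± 0.52 (exact p = 0.405). Without vehicle replicate 4 the median of the rising genes was 0.082, and it was -0.024 without vehicle 2 and -0.058, -0.048, -0.05 and -0.037 without farnesol 6, 7, 8 and 10.

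**Figure D4:**
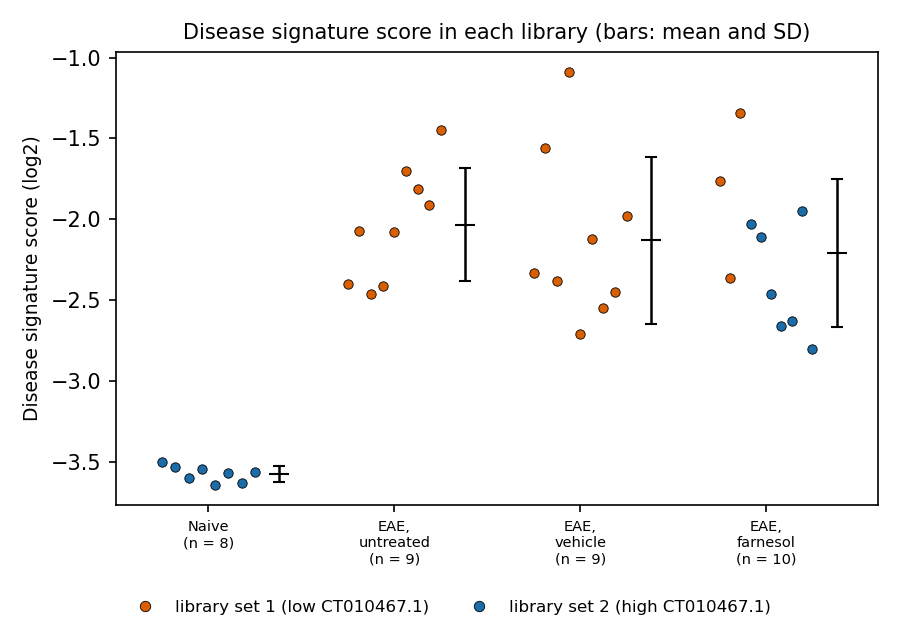
Disease signature score in each library. Scores ran from -2.80 to -1.34 with farnesol, from -2.71 to -1.09 with vehicle and from -3.64 to -3.50 in naive brains, from which the signature was taken.

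Farnesol against no gavage gave more calls, with stress and activity genes among the falls. Farnesol was given in corn oil by gavage, so its effect is not told apart from that of gavage in this comparison. Hspa5 fell by 0.50 ± 0.07, from 378 ± 29.7 (n = 9) to 267 ± 40.2 CPM (n = 10; adjusted p = 0.000141). Dnajb1 fell by 0.34 ± 0.05, Manf by 0.36 ± 0.06 and Creld2, a chaperone-associated secreted protein, by 0.48 ± 0.08. Of 20 heat shock and unfolded protein genes 0 rose, 14 fell and 6 did not pass (15 fell adjusted over the list alone). The score was 5.96 ± 0.10 against 6.24 ± 0.07, with 10 of 10 farnesol libraries below the lowest untreated one (exact p = 2.17e-05, adjusted p = 0.000509). Inside set 1 that score difference was -0.19 with 3 farnesol libraries (exact p = 0.00455, the smallest possible; adjusted p = 0.214). Both this list and the immediate early genes held in camera with an estimated correlation (adjusted p = 0.00136 and 0.0293). Vehicle libraries, also gavaged, scored 6.03 ± 0.11 for the heat shock list. Inside set 1 farnesol differed from vehicle by 0.02 in that score (exact p = 0.786, adjusted p = 0.917).

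Of 18 immediate early genes 0 rose, 9 fell and 9 did not pass (13 fell adjusted over the list alone). The score was 4.81 ± 0.18 against 5.35 ± 0.25 (exact p = 2.17e-05, adjusted p = 0.000509; -0.49, exact p = 0.0136 and adjusted p = 0.32 inside set 1). Arc, which regulates glutamate receptor trafficking (chr15:74669083-74672570), fell by 0.89 ± 0.20, from 200 ± 54.6 to 108 ± 25.6 CPM (adjusted p = 0.0111). Egr2, a zinc finger transcription factor, fell by 1.18 ± 0.27, Egr1 by 0.61 ± 0.13, Nr4a3, an orphan nuclear receptor, by 0.75 ± 0.17, Fosb by 0.74 ± 0.16. Fos fell by 0.86 ± 0.23, from 36 ± 15.2 to 19.9 ± 6.81 CPM. Cdkn1a, the cell cycle inhibitor p21, fell by 0.83 ± 0.15, and Depp1, a FOXO target of autophagy, by 1.02 ± 0.24. Untreated replicates 1 to 5 also carried transcripts of Sbp, a spermine-binding protein (3.93 to 12.4 CPM), that were at most 0.0987 CPM in replicates 6 to 9 and in all farnesol libraries. Fos measured 20.9 to 27.1 CPM in those 5 and 41.5 to 66.8 CPM in the other 4, against 12.6 to 32.9 CPM with farnesol. Without the Sbp libraries Hspa5 (-0.55), Fos (-1.34), Arc (-1.22), Egr1 (-0.78) and Nr4a3 (-1.02) still passed, and Cdkn1a (-0.61) and Fosb (-0.72) no longer did. The untreated libraries left out had the lower immediate early scores, at 5.1 to 5.34 against 5.42 to 5.8 in those kept. Leaving them out thus favoured larger falls of Fos and of the immediate early score.

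In all, 345 genes changed between farnesol-treated and untreated EAE (177 rose, 168 fell; 81 rises and 6 falls by more than 2-fold). With predicted loci left out, large rises included CT010467.1 (2.18 ± 0.30), Rn7sk (2.09 ± 0.28), Lars2 (1.72 ± 0.23), Lncpint (1.42 ± 0.19) and Malat1 (1.01 ± 0.15). Naive brains, also of set 2, lay above vehicle by 1.48 for Rn7sk and 1.13 for Lars2, and by 0.31 for Lncpint and 0.11 for Malat1. Gkn3, a gastrokine of arterial endothelium, rose by 0.94 ± 0.22, from 1.13 ± 0.478 to 2.22 ± 0.782 CPM, and mt-Atp6 by 0.81 ± 0.13. Cd74 (-0.55), Gfap (-0.36), Aif1 (-0.12), Mbp (0.02), Fdps (0.53) and Ppargc1a (0.07) did not pass. Over all libraries 2 list scores passed, heat shock and immediate early genes. Without the libraries with Sbp 4 list scores passed, heat shock (-0.27), immediate early (-0.77), B cell (-0.80) and fibroblast genes (-0.24), each at adjusted p = 0.0117 (exact p = 0.000999, the smallest possible, 10 against 4 libraries). Untreated libraries left out had B cell scores of 0.66 to 1.19, against 1.9 to 2.11 in the 4 kept. Their immediate early scores were 5.1 to 5.34, against 5.42 to 5.8 in those kept. This exclusion, made after seeing the data, thus favoured lower B cell and immediate early scores with farnesol. MHC class II (-1.11, adjusted p = 0.157) and type I interferon genes (-0.84, adjusted p = 0.15) did not pass there by exact test. Inside set 1, with 3 farnesol libraries, 1 gene was called, and Hspa5 (-0.33), Fos (-0.93) and Arc (-0.88) were not. The count of 345 was 216 without untreated replicate 2, 210 without untreated 8 and 217 without farnesol 8.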

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

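Each library was compared with the median of its group for list scores, total count and mitochondrial share, and 23 of 196 groups held a library far from the others, where chance marks about 1 in 20 groups. The tests of the Sbp libraries, of the library sets and of the random splits were chosen after seeing the results, while the predictions for disease severity and dissection were written before those tests were run.

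Regional differences included cerebellum, where the scores of naive 4 (-3.36), untreated 3 (-2.38) and farnesol 2 (-3.45) lay below their group medians. In farnesol 2 hindbrain was lower (-2.18) and olfactory bulb higher (0.91), with thalamus at -0.26. Untreated 2 was low in hindbrain (-1.08), thalamus (-0.81), myelin (-0.59) and pericyte genes (-0.26) and high in heat shock genes (0.16). Farnesol 5 was low in striatum (-0.96), and vehicle 1 in hypothalamus (-1.11). Pituitary genes stood out in untreated 3 (4.43) and vehicle 8 (4.35), where Prl reached 383 and 568 CPM. Other values were B cells in naive 8 (-0.46), endothelial activation in farnesol 3 (0.3), mevalonate genes in farnesol 1 (-0.3), respiratory chain (-0.35) and ribosomal protein genes (-0.31) in naive 5, and mitochondrially encoded transcripts in naive 3 (0.42). The total count of untreated 1 was 14.71 M, against a group median of 20.36 M (-5.65), and the mitochondrial share of untreated 7 lay 1.27 points higher.

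The rises between farnesol and vehicle were followed by library set, in part a circular test since the sets were defined by 1 of those genes. Rising genes other than CT010467.1 differed from vehicle by a median of 0.29 (0.14 to 0.39) in farnesol libraries of set 1 and by 1.03 (0.84 to 1.88) in those of set 2. The smaller difference in set 1 leaves library set as a possible explanation for part of their size. They were 0.64 higher in naive than in vehicle brains, with 13 of 14 higher in naive. The genes were picked as low in the same vehicle libraries, which favours that sign, so this count does not decide for library set. Malat1 (0.11) and Kcnq1ot1 (-0.08) did not follow set in naive brains, and the gene by gene cause was not tested. Set 1 held the farnesol replicates numbered first, and such a set of first or last numbers arises by chance in 2 of 120 ways (0.0167), so library preparation in numbered order is a possible explanation. Inside set 1, 13 of 14 were also higher with farnesol, but these libraries took part in picking the genes, which favours that sign. An effect of farnesol therefore cannot be told apart from library set.

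The slightly lower disease genes with farnesol were weighed against library set and against spread between animals. Inside set 1 the signature score differed by 0.31 in the other direction, with 3 farnesol animals, which leaves library set open and cannot be told apart from chance in so few. Spread between animals is a possible explanation, since the score over all animals gave exact p = 0.727.

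The lower heat shock score with vehicle gavage was weighed against 3 explanations. Leaving out the libraries with Sbp it was -0.21 (exact p = 0.0238, 6 against 4 libraries), and among those with Sbp -0.19. Sbp is therefore unlikely to make it. With the disease signature score as a covariate, standing in for severity, it was -0.2. That score differed by only -0.1 between the groups (exact p = 0.65), with a slope of 0.11, so the adjustment could hardly have moved the difference. Severity measured by this score is unlikely to make it, and severity by clinical score was not tested. Without libraries low in cerebellar genes it was -0.22 (exact p = 0.00062). This value leaves out only untreated 3, and leaving out any 1 library could not have halved the difference. Dissection therefore cannot be told apart from an effect of gavage. The cerebral cortex score (-0.16, exact p = 0.0133) did not pass after adjustment over the lists and does not decide this. Both groups lay in set 1, and an effect of gavage or handling remains a possible explanation that was not tested.

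Random splits of the libraries, 100 for each comparison with the real one included, asked how often as many calls arise without the real grouping. For genes against naive, 1 of 100 splits, the real one, gave as many calls in each comparison. The calls were 4586 for untreated (highest other 1406), 5808 for vehicle (highest other 1634) and 6297 for farnesol (highest other 11). That is the smallest share that 100 splits can show, so chance is unlikely there. For vehicle against untreated 2 of 100 splits gave as many calls (4, highest other 4), for farnesol against vehicle 2 (17, highest other 664) and for farnesol against untreated 2 (345, highest other 428). These shares lie below 1 in 20, but for each of them another split called as many genes or more. Chance is unlikely there too, but less clearly so. The split calling 664 genes points to a structure of the samples. Random splits mix the library sets, whereas the real farnesol group holds all 7 libraries of set 2 in its comparisons with vehicle and untreated brains, so these splits do not exclude library set. The same holds for untreated and vehicle against naive. The 4 calls of vehicle against untreated were also 0 without 1 library in 9 of 18 cases. For the number of lists passing camera chance cannot be excluded in any comparison. As many lists passed in 7 splits (29, highest other 31), 27 splits (26, highest other 32) and 10 splits (27, highest other 28) for untreated, vehicle and farnesol against naive. They did in 87 splits (11, highest other 35) for vehicle against untreated, 85 (9, highest other 29) for farnesol against vehicle and 84 (9, highest other 33) for farnesol against untreated. Chance cannot be excluded for the signature either, where a camera p as small arose in 75 splits for rising genes (0.00451, smallest other 6.49e-63) and 28 for falling genes (1.48e-05, smallest other 7.64e-20).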

How the results depend on the processing

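Alternatives that use library set, Sbp or cerebellar genes were chosen after seeing the data, and the others were fixed before the data were examined. For untreated against naive brain, a replicate block gave 2353 genes and set as a term 175. Leaving out 1 library gave 3688 to 4667. For vehicle against naive, set as a term gave 684. Leaving out 1 library gave 5085 to 5766, and for farnesol against naive 5628 to 6463. For vehicle against untreated, where 4 genes were called, the count was 7 with RLE, 7 with a mean CPM filter, 1 without cerebellum-low libraries, 0 without Sbp libraries (1437 at unadjusted p below 0.05). It was 11 with set as a term, 11 with 1 surrogate variable, 43 with DESeq2, and 15 with voom. It was 1 with a replicate block, 1 in a fit of the groups compared, and 0 to 15 leaving out 1 library. For farnesol against vehicle, where 17 were called, it was 7 without Sbp libraries, 1 with set as a term, and 4 with 1 surrogate variable. It was 42 with DESeq2, 17 with voom and 4 with a replicate block. It was 8 in a fit of the groups compared, 0 inside set 1 (2227 at unadjusted p below 0.05), 187 against the pooled vehicle and untreated control, and 8 to 36 leaving out 1 library. For farnesol against untreated, where 345 were called, it was 567 without cerebellum-low libraries, 225 without Sbp libraries, 56 with set as a term, and 589 with 1 surrogate variable. It was 521 with DESeq2, 42 with a replicate block, 128 in a fit of the groups compared, 1 inside set 1, and 210 to 500 leaving out 1 library. Lists passing camera with an estimated correlation were 2 for untreated, 2 for vehicle and 2 for farnesol against naive, 1 for vehicle against untreated, 0 for farnesol against vehicle and 2 for farnesol against untreated. Fry passed 1, 0 and 2 in the last 3. Without cerebellum-low libraries 18 lists passed for vehicle and 15 for farnesol against untreated, and without Sbp libraries 22 and 19. With set as a term 17 passed for farnesol against vehicle, and inside set 1 16 for farnesol against untreated. List scores passing by exact permutation were 0 for farnesol against untreated inside set 1, where the smallest possible p (0.00455) gives a single list an adjusted p of 0.214. Without Sbp libraries they were 0 for vehicle and 4 for farnesol against untreated. For the rising signature genes (median -0.07) an estimated correlation (p = 0.639) and fry (p = 0.74) change only the test, and neither passed. The median was -0.02 for all genes past the threshold (p = 0.047). It was 0.054 for a vehicle signature in farnesol against untreated, 0.024 with a replicate block, and 0.219 inside set 1. It was 0.018 without Sbp libraries, 0.07 for a set 2 signature in vehicle against untreated, and -0.167 to 0.082 leaving out 1 library. For the falling genes (median 0.023) neither test passed (p = 0.259 and 0.184). The median was 0.015 for all genes past the threshold (p = 0.00297), 0.008 with a replicate block and 0.014 without Sbp libraries. It was -0.035 for the vehicle signature, -0.031 inside set 1, -0.053 for the set 2 signature, and 0.007 to 0.031 leaving out 1 library. With set as a term, CT010467.1 turned to 0.31 in untreated and 0.28 in vehicle against naive, Rn7sk to 0.27 and 0.31, and Lars2 to 0.71 in vehicle against naive. The cause of the library sets was not tested.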

Other observations

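The structure described in this part was found after seeing the data, as were the tests that leave out libraries with Sbp, and the ranges given here were not tested. Sbp, a spermine-binding protein known from mouse prostate (chr17:23941672-23945607), was above 1 CPM only in untreated replicates 1 to 5 (3.93 to 12.4 CPM) and vehicle replicates 3 to 5 (5.17 to 7.97 CPM), and Sbpl, its neighbour, followed it. The untreated libraries with Sbp differed from the other 4 in immune and stress genes. B cell scores were 0.66 to 1.19 with Sbp and 1.90 to 2.11 without, T cell scores 0.38 to 0.76 and 1.07 to 1.45, and type I interferon scores 2.15 to 3.06 and 3.68 to 3.98. MHC class II scores were 2.88 to 3.88 and 4.19 to 4.83, and complement scores 3.33 to 3.99 and 4.35 to 4.56.

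Glucocorticoid response scores ran the other way, at 4.66 to 5.06 with Sbp and 4.07 to 4.45 without. Fkbp5, a cochaperone of the glucocorticoid receptor chosen after the values were seen, measured 55.7 to 76.7 CPM with Sbp and 27.3 to 34.6 CPM without, against 24 to 32 CPM in naive brains. Gfap was 347 to 527 CPM with Sbp and 704 to 988 CPM without. Neutrophil scores overlapped, at 1.21 to 2.65 and 1.79 to 2.84. In all, 14 of 47 list scores did not overlap between these untreated libraries, and 0 of 47 did so among the vehicle libraries. For a given list 1.59% of random splits of the untreated libraries would not overlap. List scores can vary together between animals, so the 14 lists are not separate pieces of evidence.

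All libraries had the pattern of females by sex-linked genes, with high Xist and at most 3 counts from the Y chromosome genes examined. Xist was 317 to 515 CPM in naive libraries and 541 to 832 CPM in EAE libraries. Library replicate numbers carried no pairing, with a median correlation between same-numbered libraries of -0.02 to 0.05. Set as a term in the fit was itself called in 73 genes (38 higher, 35 lower), and the surrogate variable correlated with it at 0.43. Only the farnesol group held both sets, so the term rests on those libraries.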
